A study of Homo sapiens with 8 samples.

How the data were processed

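The libraries came from immortalized human cardiac fibroblasts carrying either a short hairpin RNA against EIF4G2 or a scrambled hairpin. The cells were kept without serum for at least 6 h and then treated with TGF-beta for 24 h, per the labels' protocols. Total RNA and polysomal RNA were each sequenced as 2 libraries per hairpin, which gave 8 libraries in 4 groups. Groups and replicate numbers were taken from the sample labels alone. The series' design text speaks of more replicates per group than the 2 analysed here. How the polysomes were isolated, and which part of the EIF4G2 transcript the hairpin targets, were not given in the sources used here.

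The values are counts per gene that the authors deposited as whole numbers for 59385 gene symbols, without normalization. Per the series' design text, RNA was treated with DNase, polyadenylated RNA was enriched and paired-end reads were made on an Illumina NovaSeq instrument. The submitters' processing notes name bcl2fastq 2.19.0, Trimmomatic 0.36, HISAT2 2.1.0, Subread 2.0.1, featureCounts, DESeq2 and R 4.1.2, and the GRCh38 genome build, with no order or options. The gene annotation, the strand setting and the treatment of reads with several matches were not given in the sources used here. Counts of genes with near-identical copies, such as ribosomal protein genes and their pseudogenes, and of overlapping or antisense genes are therefore uncertain. PolyA enrichment also means that RNAs without a long tail are poorly covered. Each library was scaled by its own total and a TMM factor. A level in polysomal RNA is therefore relative to other genes and not an amount of ribosome-bound mRNA per cell. TMM factors ran from 1.368 to 1.453 in total and from 0.6528 to 0.7508 in polysome libraries. TMM assumes that most genes do not differ, so the baseline of fold changes between polysomal and total RNA rests on this scaling.

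All symbols named a gene, and no symbol was left out of the library totals. Genes were kept with filterByExpr over the 4 groups, which left 16228 tested genes, and libraries were scaled by TMM. Counts were fitted with edgeR 4.0.16 (R 4.3.3) in a quasi-likelihood model with robust dispersion estimates and a mean for each group. All 8 libraries shared the fit, which has 4 residual degrees of freedom and a typical prior of 6.85. The tests were the knockdown against scramble in total RNA, in polysomal RNA and in their ratio (the interaction of hairpin and fraction), and polysomal against total RNA in scramble and in knockdown cells. P-values were adjusted by Benjamini-Hochberg over the tested genes, with a threshold of 0.05. Standard errors of log2 fold changes were the fold change divided by the square root of the quasi-likelihood F statistic. Levels are CPM of the TMM-scaled library, and log2 CPM used a prior count of 2. DESeq2 1.42.0 (Wald test) was run on the same genes and groups as an alternative, and its adjusted p was left missing where DESeq2 gave none.

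A total of 26 gene lists with 902 genes were fixed before the data were examined, as were the tests, the sample groups, the rule for named genes and all alternatives except those said to be added. The lists covered extracellular matrix structure, collagen folding and crosslinking, the myofibroblast contractile apparatus, TGF-beta signalling, integrins and focal adhesion, and matrix proteases and inhibitors. Further lists covered growth factor receptors with MAPK-AKT signalling, WNT with Hippo-YAP signalling, the integrated stress and unfolded protein response, cytosolic ribosomal proteins, translation factors other than EIF4G2, and mRNAs reported to use EIF4G2 at internal ribosome entry sites. Cell cycle, p53 targets, nuclear-encoded oxidative phosphorylation, mitochondrially encoded mRNAs, long non-coding RNAs, the secretory pathway, the interferon response and cytokines were also listed. The last 6 lists held markers of fibroblasts, cardiomyocytes, endothelial cells, leukocytes, mural cells, and epithelial and embryonic kidney lines. Lists were tested with camera (limma 3.58.1) at its preset correlation of 0.01. P-values were adjusted over the 78 tests of the 3 knockdown comparisons, and over the tests of both fraction comparisons as a separate family. Camera with an estimated correlation and fry were the alternatives. Camera asks whether a list moved relative to other genes, and fry whether its members moved on balance in 1 direction.

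The rule for named genes took EIF4G2, the 8 genes with the largest positive and the 8 with the largest negative log2 fold change among called protein-coding genes, and the 3 members of each list with the smallest p. Called genes needed a mean log2 CPM of at least 3 and both libraries of a group on the same side of both libraries of the other. Members are named here for the lists that passed and for matrix, contractile and TGF-beta lists. The rule was also applied to the DESeq2 calls of the knockdown comparisons, which was decided after edgeR was seen to call 2 genes. COL1A1, EME2, CDIP1, the genes called in both fractions and list members named as called over a list alone were chosen after their values were seen. Genes on the Y chromosome and XIST were left out of the text, and some genes that the rule took are not reported here.

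Transcript length, GC content, gene type and position came from GENCODE release 29 on GRCh38. A match was found for 40136 symbols (67.6%), which held 99.7% of counts. Of these, 2374 matched through a current or older symbol, and 97 had more than 1 gene identifier. Length was that of a single coding transcript per gene, the one with the longest coding sequence among those with consensus support. Smooth trends were fitted with mgcv 1.9.3.

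Each test was checked on simulated counts drawn for the real genes from the real means and library sizes, with 50 genes changed at each of 4 fold sizes. The changed genes and the members of simulated lists were drawn from genes with a mean log2 CPM above 2. Recovery of genes at lower levels was therefore not measured. Each gene had the same simulated spread in both fractions, taken from the fit of all 8 libraries. The wider spread of polysome libraries (coefficient of variation 0.265, against 0.181 in that fit) was not simulated. Recovery and false calls in polysomal RNA and the ratio may therefore be worse than given here. In total RNA, edgeR recovered 72% of genes changed 2-fold and 100% of those changed 4-fold, with 10 false calls among 15540 unchanged genes. In polysomal RNA it recovered 70% and 98% with 7 false calls, and in the ratio 28% and 94% with 11. For polysomal against total RNA it recovered 64% and 100% in both kinds of cell, with 9 false calls in scramble and 6 in knockdown cells. DESeq2 made 28, 19 and 19 false calls in the total, polysomal and ratio comparisons, and 34 and 19 in the fraction comparisons, so its share of false calls lay above the nominal level in each comparison, as did that of edgeR in total RNA, the ratio and the scramble fraction comparison. A simulated list shifted in knockdown polysomes had a camera adjusted p = 1.07e-28, or 0.0102 with an estimated correlation, and 0 of 25 unchanged lists were called. Simulated genes were drawn independently, whereas real list members varied together, with an estimated correlation of 0.752 for ribosomal proteins in total RNA. The list check therefore does not cover false calls that come from such correlation. A length trend put into 1 simulated total library gave a Spearman correlation of −0.535 between fold change and length, which the length correction brought to −0.0116.

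The alternatives were DESeq2 size factors in place of TMM, no filter on low counts, DESeq2's test, the replicate number as a block, glmTreat against a 1.5-fold change, fits of the 4 libraries of a comparison alone, and leaving out each library in turn. Chosen after seeing the data were a correction for transcript length, a correction for length and GC content together, leaving out mitochondrially encoded genes, and rerunning the list tests without each library. In the length correction, the trend of each library's log2 CPM against the mean of its fraction was smoothed on log10 transcript length and used as an offset. Figures were drawn with matplotlib 3.10.9 in python 3.11.15, with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Counting intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.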

Results

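Total and polysomal RNA was measured in immortalized human cardiac fibroblasts (IHCF), a line of the cells that lay down matrix in the heart, after knockdown of EIF4G2. EIF4G2, also called DAP5, is a relative of the translation scaffold EIF4G1 that lacks the part which binds the cap-binding protein eIF4E. All cells had received TGF-beta, the cytokine that turns fibroblasts into contractile, matrix-secreting myofibroblasts, so no comparison here measures the response to TGF-beta itself. The question put to the data was which mRNAs, those of fibrosis among them, depend on EIF4G2 for their level or for their place in polysomes, the mRNAs loaded with several ribosomes. The labels name no further hairpin against EIF4G2 and no rescue. Other effects of the hairpin therefore cannot be told apart from loss of EIF4G2 in any comparison here. Each of the 4 groups (scramble total, knockdown total, scramble polysome and knockdown polysome) held 2 libraries. The labels call these biological replicates, and nothing beyond that says that they came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

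Depth was similar across libraries. Scramble total replicates 1 and 2 held 20661662 and 18519382 counts, and knockdown total replicates 1 and 2 held 23299332 and 20906692. Scramble polysome replicates 1 and 2 held 24590030 and 24130489 counts, and knockdown polysome replicates 1 and 2 held 21138829 and 18043714. The leading principal component of the 16228 tested genes took 89.1% of the variance and separated polysomal from total libraries. On the next component (4.05%) knockdown polysome replicate 1 stood apart at −45.6, against −2.46 to 20.3 in the other libraries. The component after that (2.71%) set scramble polysome replicate 1 (−31.1) and knockdown polysome replicate 2 (30.0) apart, against −2.47 to 3.90 in the remaining libraries. Mitochondrially encoded genes took 3.88 to 4.21% of counts in total libraries, 7.12% in scramble polysome replicate 1 and 14.5 to 17.5% in the other 3 polysome libraries. Ribosomal protein mRNAs took 12.7 to 17.9% of counts in polysome libraries and 4.27 to 5.66% in total libraries, with the highest total share in knockdown total replicate 1. That library also had the shortest median transcript length per count among total libraries, 2705 nt against 2982 to 3033 nt. Pearson's r of log2 CPM across genes was 0.995 between the scramble total replicates, 0.985 between the knockdown total, 0.975 between the scramble polysome and 0.966 between the knockdown polysome replicates. Counts of the replicates differed beyond sampling noise in every group, with a chi-square per degree of freedom of 2.69 in scramble total, 26.7 in knockdown total, 135 in scramble polysome and 42.4 in knockdown polysome libraries. The biological coefficient of variation was 0.265 in polysome and 0.113 in total libraries.

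EIF4G2 was lower in both kinds of knockdown library. The gene lies on chromosome 11 of GRCh38, from 10797050 to 10809110 on the minus strand. In total RNA it stood at 789.4 ± 6.00 CPM in scramble and 310.3 ± 23.9 CPM in knockdown cells (SD, n = 2), which left 39.3% of the scramble level. The log2 fold change was −1.35 ± 0.18 (SE), with an adjusted p = 0.0504 by edgeR, just above the threshold, and an adjusted p = 4.05e-10 by DESeq2. In polysomal RNA EIF4G2 fell from 876.2 ± 1.21 to 289.3 ± 64.1 CPM, leaving 33.0% (log2 fold change −1.60 ± 0.18, edgeR adjusted p = 0.0276). The ratio of polysomal to total EIF4G2 mRNA had a log2 difference of −0.25 ± 0.25 between knockdown and scramble (edgeR adjusted p = 0.894), which was −0.06 without knockdown polysome replicate 1 and −0.54 without knockdown polysome replicate 2. EIF4G1, the canonical scaffold, stood at 615.4 and 615 CPM in scramble total and 540 and 600.3 CPM in knockdown total libraries. In polysomes EIF4G1 stood at 54.03 and 81.04 CPM in scramble and 41.46 and 48.33 CPM in knockdown libraries (log2 fold change −0.59 ± 0.20, edgeR adjusted p = 0.264). With 1 library left out, the edgeR adjusted p of the polysomal EIF4G2 fold change lay above the threshold for knockdown total replicates 1 (0.207) and 2 (0.224), scramble polysome replicates 1 (0.102) and 2 (0.107) and knockdown polysome replicate 1 (0.131), with log2 fold changes from −1.91 to −1.42 over all such fits.

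**Figure D1:**
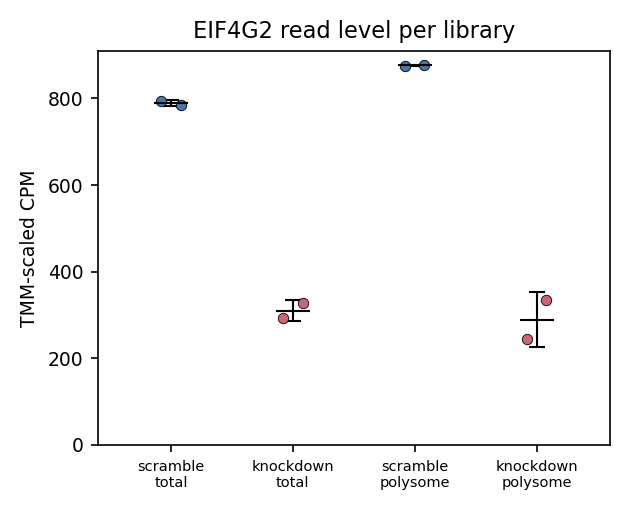
EIF4G2 level in TMM-scaled CPM (linear axis from 0) in each of the 8 libraries, by group, with points for libraries and lines for the mean ± SD of 2. All 4 knockdown libraries (244 to 334.6 CPM) lie below all 4 scramble libraries (785.2 to 877 CPM).

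In total RNA, the genes called higher in knockdown cells by DESeq2 included H2AX and HMGA2, and those called lower included BGN and HMGCS1. H2AX, the histone variant that marks DNA breaks, went from 162.5 ± 2.93 to 356.8 ± 34.5 CPM (SD, n = 2; DESeq2 log2 fold change 1.12 ± 0.14, adjusted p = 8.73e-11). HMGA2, an architectural chromatin protein, went from 9.23 ± 0.316 to 24.3 ± 3.01 CPM. BGN, the small matrix proteoglycan biglycan, went from 49.5 ± 2.13 to 26.6 ± 2.48 CPM, and HMGCS1, an enzyme of cholesterol synthesis, from 69.0 ± 2.84 to 42.0 ± 2.72 CPM. None of these passed edgeR's test.

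DESeq2 called 26 genes in total RNA, 19 higher and 7 lower, EIF4G2 included. edgeR called 0, with 598 genes at an unadjusted p under 0.05 where chance alone gives 811. That fit shared 1 spread over all 8 libraries (coefficient of variation 0.181, against 0.113 in total and 0.265 in polysome libraries), and with the 4 total libraries alone edgeR called 10 genes, with 2124 of 15500 at an unadjusted p under 0.05. The lowest edgeR adjusted p, 0.0504, was shared by EIF4G2, H2AX, HSD17B10, NCEH1 and ID3. The largest positive log2 fold changes, as edgeR estimates, among the DESeq2 calls named by the rule were 1.40 for HMGA2, 1.37 for HSD17B10, a mitochondrial dehydrogenase, 1.26 for NCEH1, a cholesterol ester hydrolase, and 1.25 for ANGPTL4, a secreted inhibitor of lipoprotein lipase. ID3, a target of BMP signalling that inhibits DNA binding by other factors, had a log2 fold change of 1.18, DYNLL2, a dynein light chain, 1.17, and SPHK1, a sphingosine kinase, 1.05. On the lower side stood BGN at −0.90, HMGCS1 at −0.72, TMEM181 at −0.71, the sterol sensor INSIG1 at −0.64 and the fatty acid desaturase SCD at −0.57. VEGFA, the vascular growth factor, went from 52.9 ± 1.95 to 97.9 ± 10.1 CPM (DESeq2 adjusted p = 0.00273).

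Among the fixed lists, interferon response genes fell in total RNA, with 26 of 31 members below 0 and a median log2 fold change of −0.43 (camera adjusted p = 3.42e-08; adjusted p = 0.464 with an estimated correlation). IFIT2, MX1 and OASL, all antiviral effectors, had log2 fold changes of −0.59, −0.62 and −0.51. Genes of the integrated stress and unfolded protein response rose, with 31 of 38 members above 0 and a median of 0.23 (camera adjusted p = 2.74e-07; adjusted p = 0.464 with an estimated correlation). Of its members edgeR called 2 higher, adjusted over the list alone, CHAC1, which degrades glutathione (4.02 ± 0.967 to 7.58 ± 0.053 CPM), and SLC7A11, the cystine transporter (4.13 ± 0.396 to 10.1 ± 0.185 CPM). CEBPB, a transcription factor of that response, had a log2 fold change of 0.52. Both the interferon and the stress list stayed called without each library in turn.

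Cytosolic ribosomal protein genes (75 of 76 members above 0, median 0.24, camera adjusted p = 2.74e-07; adjusted p = 0.904 with an estimated correlation) and nuclear-encoded genes of oxidative phosphorylation (67 of 70 above 0, median 0.21, camera adjusted p = 8.09e-06; adjusted p = 0.904 with an estimated correlation) also rose as lists. These rises rested on knockdown total replicate 1, the library with the shortest transcripts and the highest ribosomal protein share. Against the scramble mean, the ribosomal protein median was 0.47 in that library and −0.04 in knockdown total replicate 2, and the oxidative phosphorylation median was 0.44 and −0.07. Without knockdown total replicate 1 both lists turned downward and were not called (camera adjusted p = 0.173 and 0.277). RPS21 had a log2 fold change of 0.46 ± 0.26, which became −0.02 without that library and 0.81 without knockdown total replicate 2. RPLP1 had 0.44 and RPS27A 0.40, and these were 0.17 and 0.11 without knockdown total replicate 1. ATP5F1D, NDUFB2 and ATP5PO, subunits of ATP synthase and complex I, had 0.41, 0.47 and 0.43, and 0.19, 0.27 and 0.08 without it. With the trend on transcript length removed, an alternative chosen after seeing the data, neither list passed camera (adjusted p = 0.0525 for ribosomal proteins and 0.126 for oxidative phosphorylation). With length and GC content removed together, ribosomal proteins kept the call and oxidative phosphorylation did not (camera adjusted p = 0.056).

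Cytokine genes rose as a list, with 24 of 35 members above 0 and a median of 0.16 (camera adjusted p = 0.0177; adjusted p = 0.464 with an estimated correlation). Of the cytokine list edgeR called 2 members higher, adjusted over the list alone, VEGFA and ANGPTL4, both also called by DESeq2. Markers of mural cells (7 of 8 below 0, median −0.27) and of epithelial and embryonic kidney lines (7 of 8 below 0, median −0.54) fell (camera adjusted p = 0.0261 and 0.0262; adjusted p = 0.532 for both with an estimated correlation). The cytokine call was lost without scramble total replicate 1 (camera adjusted p = 0.05, rounded) and knockdown total replicates 1 (0.0940) and 2 (0.0795), and with the length trend removed (0.0525). The mural call was lost without the same 3 libraries (camera adjusted p = 0.0832, 0.169 and 0.0795), and the epithelial call without scramble total replicate 2 (0.0960) and knockdown total replicate 2 (0.581). With length and GC content removed together, the cytokine list kept its call. For the interferon, ribosomal protein, oxidative phosphorylation, mural and epithelial lists, edgeR called 0 members adjusted over the list alone, with 5, 0, 3, 0 and 1 members at an unadjusted p under 0.05, and DESeq2 called 0 in each.

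The matrix and contractile lists did not pass in total RNA. Extracellular matrix genes had 22 members above and 23 below 0 (median −0.0053, mean 0.03, camera direction up, adjusted p = 0.945), and contractile genes 20 above and 18 below (median 0.01, mean −0.0040, camera direction up, adjusted p = 0.915). Among matrix genes edgeR called LUM, the proteoglycan lumican, higher and BGN lower, and 0 contractile genes, each adjusted over the list alone, with 3 contractile genes at an unadjusted p under 0.05 and 0 by DESeq2. FZD7, a WNT receptor, and NF2, the tumour suppressor merlin, were called higher in the WNT and Hippo-YAP list, adjusted over the list alone, and by DESeq2. In the fibroblast list LUM was called, adjusted over the list alone, and in the other 16 uncalled lists edgeR called 0 members, with 0 to 4 at an unadjusted p under 0.05 and 0 by DESeq2. The 19 lists not called in total RNA had camera adjusted p-values from 0.125 to 0.966. Median, mean and test differed in sign in total RNA for the matrix, contractile, integrin, internal ribosome entry site, secretory, fibroblast, endothelial and leukocyte lists, and for 0 of the 7 called lists.

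In polysomal RNA, STC1 rose and EIF4G2 fell by edgeR's test, and DESeq2 called 228 genes, 94 higher and 134 lower. STC1, the secreted hormone stanniocalcin, went from 2.68 ± 0.507 to 10.9 ± 0.156 CPM (SD, n = 2; log2 fold change 2.01 ± 0.23, edgeR adjusted p = 0.0276). The higher DESeq2 calls included TNFRSF11B, which encodes osteoprotegerin, at 5.46 ± 1.28 and 19 ± 1.41 CPM. The lower DESeq2 calls included the actin crosslinkers FLNA (302.5 ± 4.41 to 170.0 ± 59.2 CPM) and FLNC (22.1 ± 4.17 to 10.9 ± 2.46 CPM). COL1A1, the main chain of type I collagen, stood at 1338 ± 169 and 891.3 ± 9.38 CPM.

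The 2 edgeR calls stood among 2152 genes at an unadjusted p under 0.05 in the fit of all 8 libraries, where chance gives 811. Polysome libraries varied more (0.265) than the shared spread of that fit (0.181), and with the 4 polysome libraries alone edgeR called 3 genes, with 843 of 13824 at an unadjusted p under 0.05. DESeq2 also took 1 spread per gene from all 8 libraries. Neither DESeq2 nor the list tests were rerun on the 4 polysome libraries alone, so their polysomal calls may include more false ones than the threshold implies. STC1's edgeR adjusted p lay above the threshold without knockdown total replicates 1 (0.207) and 2 (0.224), scramble polysome replicates 1 (0.0958) and 2 (0.107) and knockdown polysome replicate 1 (0.118), with log2 fold changes from 1.77 to 2.20 over all such fits. Nor was STC1 called with the 4 polysome libraries alone (edgeR adjusted p = 0.163) or by glmTreat against 1.5-fold (adjusted p = 0.155). Without knockdown polysome replicate 2, edgeR called 183 genes, 56 higher and 127 lower, and it called 0, with 2200 at an unadjusted p under 0.05, without knockdown polysome replicate 1. Further count changes came without scramble total replicate 1 or 2 (5 genes each), scramble polysome replicate 1 (1 gene), and knockdown total replicate 1 or 2 or scramble polysome replicate 2 (0 genes each, with 1890, 1892 and 2755 at an unadjusted p under 0.05).

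With log2 fold changes given as edgeR estimates, DESeq2 called TNFRSF11B (1.80), ETV4 (1.35), an ETS transcription factor, ADCY3 (1.32), an adenylyl cyclase, HMGA2 (1.28), S1PR1 (1.27), a sphingosine phosphate receptor, ZSCAN25 (1.27) and SNAI2 (1.26), a transcription factor of mesenchymal cells, as higher. The SNAI2 value was 0.75 without knockdown polysome replicate 1. Lower DESeq2 calls included FAM160B2 (−2.41), the lipid transfer protein OSBPL5 (−2.14), TUB (−2.13), the desmosome protein DSP (−2.10), SOGA1 (−2.03), the microtubule protein MAP1A (−1.91) and the laminin chain LAMA1 (−1.85). DSP and SOGA1 stood at −1.12 and −1.24 without scramble polysome replicate 1, and DSP at −3.67 without knockdown polysome replicate 1. PPL, the plakin periplakin, had 29 and 30 counts in the scramble and 2 and 0 counts in the knockdown polysome libraries, a scramble to knockdown ratio of 22.2 (95% counting interval 5.89 to 188). DESeq2 called 10 genes in both total and polysomal RNA, which share no library but were tested in the same fit with a common spread per gene. The labels do not say whether both fractions came from the same cultures, so the overlap does not measure independent replication. All 10 had the same direction, 8 higher and 2 lower, where independent lists would share 0.164 and 0.0862 (Fisher's exact test, p = 5.32e-11). They were AKIRIN1, CDC42EP1, H2AX, HMGA2, HSD17B10, NCEH1, SEMA7A and TMED4 on the higher side and EIF4G2 and HMGCS1 on the lower.

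Contractile genes fell as a list in polysomal RNA, with 29 of 38 members below 0 and a median log2 fold change of −0.24 (camera adjusted p = 0.0027; adjusted p = 0.689 with an estimated correlation). Of these edgeR called 2 lower, adjusted over the list alone, among them FLNC (−1.02). DESeq2 called 3 lower, among them FLNC and FLNA (edgeR estimate −0.83; −0.55 without knockdown polysome replicate 1 and −1.30 without knockdown polysome replicate 2). Extracellular matrix genes also fell, with 33 of 45 below 0 and a median of −0.42 (camera adjusted p = 0.00501; adjusted p = 0.874 with an estimated correlation). Against the scramble polysome mean, the matrix median was −0.35 and −0.25 in knockdown polysome replicates 1 and 2. It was 0.21 and −0.21 in scramble polysome replicates 1 and 2, so scramble replicate 2 lay near knockdown replicate 2. Adjusted over the list alone, edgeR called 0 matrix genes, with 16 at an unadjusted p under 0.05, while DESeq2 called COL1A1 (edgeR estimate −0.59), the collagen VI chain COL6A3 (−1.47) and the fibulin FBLN2 (−0.99) lower. COL6A3 stood at −0.89 without scramble polysome replicate 1. COL1A2 had a log2 fold change of −1.07, which was −0.25 without scramble polysome replicate 1 and −1.66 without scramble polysome replicate 2. The matrix list was not called without scramble polysome replicate 1 (camera adjusted p = 0.564) or knockdown polysome replicate 1 (0.135), nor the contractile list without knockdown polysome replicate 1 (0.160), the library that stood apart at −45.6 on its principal component. Removing the trends on length and GC content together, chosen after seeing the data, gave the matrix list a camera adjusted p = 0.0560.

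**Figure D2:**
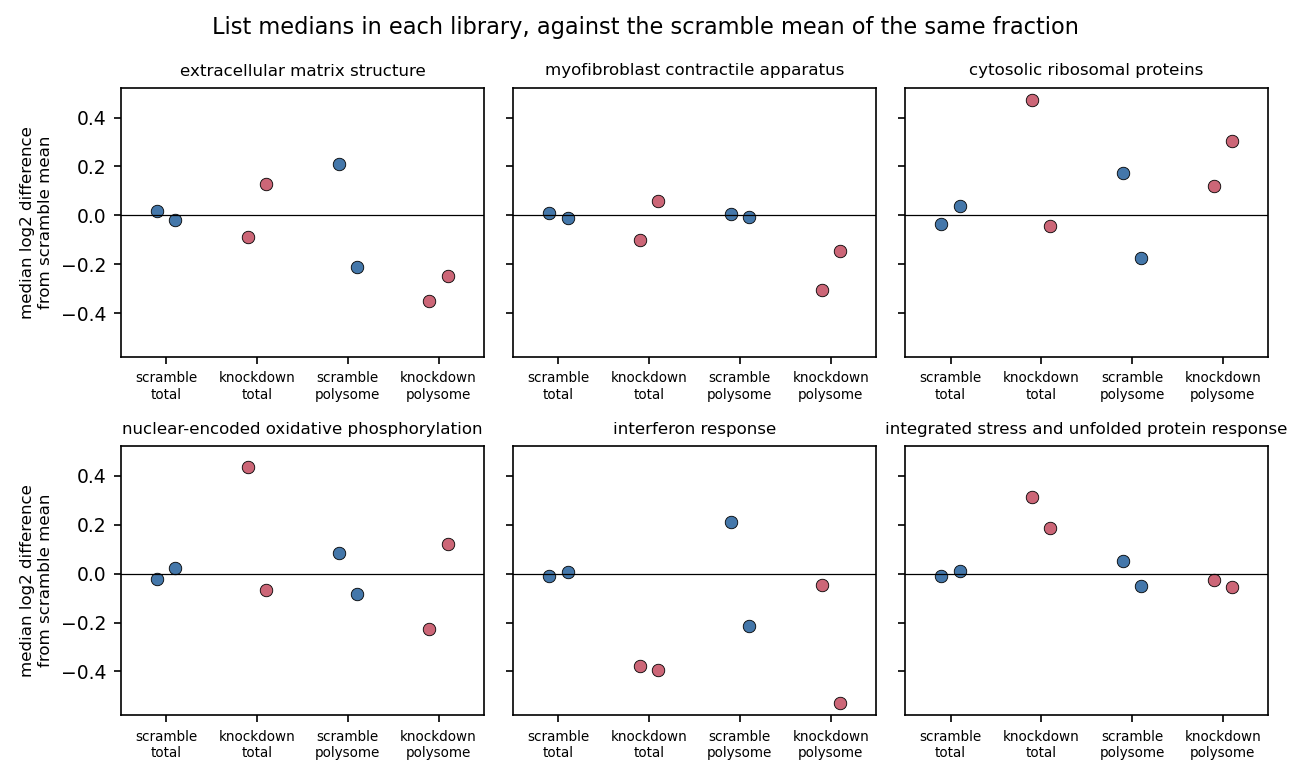
Median log2 difference of the members of 6 gene lists in each library from the scramble mean of the same fraction, with a point for each library and the groups in separate columns. In both knockdown polysome libraries the matrix list (−0.35 and −0.25) and the contractile list (−0.30 and −0.15) lie below 0. In scramble polysome replicates 1 and 2 the matrix list lies at 0.21 and −0.21, the latter near knockdown replicate 2, and the contractile list at 0.007 and −0.007. The ribosomal protein list lies at 0.47 in knockdown total replicate 1 and −0.04 in replicate 2.

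Interferon response genes fell in polysomal RNA as well, with 27 of 31 below 0 and a median of −0.30 (camera adjusted p = 0.0027; adjusted p = 0.698 with an estimated correlation). Against the scramble polysome mean, the interferon median was −0.04 in knockdown polysome replicate 1 and −0.53 in replicate 2. Replicate 1 lay inside the range of the scramble polysome replicates (0.21 and −0.21). Of the interferon genes edgeR called 1 lower, adjusted over the list alone, MX2 (−2.03; 3.93 ± 0.265 to 0.975 ± 0.423 CPM), which DESeq2 also called. OAS1 had a log2 fold change of −1.46, and −2.22 without knockdown polysome replicate 2. Cell cycle genes fell slightly, with 35 of 47 below 0 and a median of −0.16 (camera adjusted p = 0.0166; adjusted p = 0.464 with an estimated correlation), and KIF20A, E2F3 and MKI67 had −0.52, −0.53 and −0.75. MKI67, the proliferation marker, stood at −0.43 without knockdown polysome replicate 1 and −1.25 without knockdown polysome replicate 2. Epithelial and kidney line markers fell, with 7 of 8 below 0 and a median of −0.52 (camera adjusted p = 0.00387; adjusted p = 0.464 with an estimated correlation), and edgeR called KRT8, KRT18, KRT19 and CLDN4, genes of simple epithelia, lower adjusted over the list alone. The interferon call was lost without scramble polysome replicate 1 (camera adjusted p = 0.307) and knockdown polysome replicate 2 (0.451), the cell cycle call without the same libraries (0.222 and 0.167), and the epithelial call without knockdown polysome replicate 2 (0.0896).

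Ribosomal protein genes (65 of 76 above 0, median 0.19, camera adjusted p = 0.000235; adjusted p = 0.924 with an estimated correlation) and mitochondrially encoded mRNAs (13 of 13 above 0, median 0.33, camera adjusted p = 0.0027; adjusted p = 0.903 with an estimated correlation) rose in polysomal RNA. The ribosomal protein call was lost without scramble polysome replicate 2 (camera adjusted p = 0.966) and knockdown polysome replicate 2 (0.502). The mitochondrial list turned downward without scramble polysome replicate 1 (camera adjusted p = 0.307), the library with 7.12% mitochondrial counts, and was not called without knockdown polysome replicate 2 (0.181). Adjusted over the list alone, edgeR called 0 cell cycle, ribosomal protein and mitochondrial genes, with 9, 0 and 0 at an unadjusted p under 0.05, and DESeq2 called 0 in each.

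Lists of TGF-beta signalling and matrix turnover held members that moved each way in polysomal RNA and did not pass as lists. Adjusted over the list alone, edgeR called 2 TGF-beta signalling genes higher, the receptor TGFBR2 (0.62) and the oxidase NOX4 (0.85), and 4 lower, TGFBR3, LTBP3, ACVR1B and FSTL3. In the protease list it called 2 higher and 3 lower, adjusted over the list alone; the collagenase MMP1 had a log2 fold change of 0.56 and the plasminogen activator PLAT −1.0, both also called by DESeq2. Median log2 fold changes of the other uncalled lists in polysomal RNA were −0.12 for collagen folding, 0.02 for TGF-beta signalling and for integrins, −0.15 for proteases, −0.04 for growth factor receptors and 0.03 for WNT and Hippo-YAP signalling. They were −0.05 for the stress response, 0.05 for translation factors, −0.0011 for mRNAs with reported internal ribosome entry, −0.0057 for p53 targets, −0.06 for oxidative phosphorylation, −0.0035 for long non-coding RNAs, −0.03 for the secretory pathway and 0.07 for cytokines. Marker lists stood at −0.20 for fibroblasts, −0.26 for cardiomyocytes, 0.29 for endothelial cells, 0.25 for leukocytes and −0.72 for mural cells. Further members called by edgeR, adjusted over the list alone, were P3H2 (higher) for collagen folding, ITGA7, ILK and FERMT2 (lower) for integrins, CCNG1 (higher) for p53 targets and NPPB, MYL7 and ATP2A2 (lower) for cardiomyocytes. The WNT and Hippo-YAP, fibroblast and mural lists had 1 member higher each and 2, 3 and 2 lower. The other 10 uncalled lists had 0 such calls by edgeR, with 0 to 13 members at an unadjusted p under 0.05 and 0 or 1 by DESeq2. Camera adjusted p-values of these 19 lists ran from 0.123 to 0.954. Median, mean and test differed in sign in polysomal RNA for the TGF-beta signalling, integrin, growth factor receptor, translation factor, internal ribosome entry site, p53 and long non-coding RNA lists, and for 0 of the 7 called lists.

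The ratio of polysomal to total RNA asked whether the knockdown moved an mRNA in polysomes beyond its move in total RNA. DESeq2 called 4 genes there, OSBPL5 (DESeq2 log2 difference −2.17 ± 0.45, adjusted p = 0.0260), the signal peptide peptidase SPPL2B (−1.34 ± 0.30, adjusted p = 0.0338) and EME2 (adjusted p = 0.0406) as lower and CDIP1 (3.65 ± 0.81, adjusted p = 0.0338) as higher. EME2, part of a DNA endonuclease, had 32 and 20 counts in the scramble and 0 in both knockdown polysome libraries, at least 6.39-fold lower against a floor of 3 counts per library. CDIP1 rested on 0.336 ± 0.138 CPM in scramble and 2.69 ± 1.64 CPM in knockdown polysomes. edgeR called 0 genes, with 1018 at an unadjusted p under 0.05 where chance gives 811, and 2 without knockdown polysome replicate 2. On simulated counts, with the spread taken as equal in both fractions, the ratio test recovered 28% of genes changed 2-fold and 94% of those changed 4-fold. These rates hold for genes with a mean log2 CPM above 2, and lower levels were not simulated as changed.

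Of the lists, contractile genes (32 of 38 below 0, median −0.24, camera adjusted p = 0.0027; adjusted p = 0.689 with an estimated correlation) and extracellular matrix genes (37 of 45 below 0, median −0.32, camera adjusted p = 0.0127; adjusted p = 0.903 with an estimated correlation) fell in the ratio. FLNC had a log2 difference of −0.93, TAGLN, the smooth muscle protein transgelin, −0.95, and TRIP6, a focal adhesion adaptor, −0.51. TAGLN stood at −0.59 without knockdown polysome replicate 1 and −1.49 without knockdown polysome replicate 2. Among matrix genes, THBS1, which activates latent TGF-beta, had −0.95, COL11A1 −2.0 and COL1A2 −1.20, the last at −0.36 without scramble polysome replicate 1. Stress response genes (33 of 38 below 0, median −0.25, camera adjusted p = 0.00143; adjusted p = 0.551 with an estimated correlation) and oxidative phosphorylation genes (62 of 70 below 0, median −0.29, camera adjusted p = 0.00143; adjusted p = 0.924 with an estimated correlation) fell too. Both had risen in total RNA, whose libraries enter the ratio with the opposite sign, and their polysomal medians were −0.05 and −0.06. CHAC1, SLC7A5 and SLC3A2, the last pair forming an amino acid transporter, had log2 differences of −1.15, −0.69 and −0.64. Mitochondrially encoded mRNAs rose (13 of 13 above 0, median 0.33, camera adjusted p = 0.00143; adjusted p = 0.903 with an estimated correlation).

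Adjusted over the list alone, edgeR called 0 members of these 5 lists in the ratio, with 5 contractile, 6 matrix, 8 stress response, 0 oxidative phosphorylation and 0 mitochondrial genes at an unadjusted p under 0.05, and DESeq2 called 0. The matrix call was lost without scramble total replicate 2 (camera adjusted p = 0.0787), knockdown total replicate 2 (0.585), scramble polysome replicate 1 (0.565) and knockdown polysome replicate 1 (0.137), and the contractile call without knockdown total replicate 2 (0.0809) and knockdown polysome replicate 1 (0.137), which stood apart on the component noted above. Oxidative phosphorylation turned upward without knockdown total replicate 1 (camera adjusted p = 0.830) and was not called without scramble polysome replicate 1 (0.220) or knockdown polysome replicate 1 (0.454), nor with the length trend removed, chosen after seeing the data (0.0695). The mitochondrial list turned downward without scramble polysome replicate 1 (camera adjusted p = 0.711) and was not called without knockdown polysome replicate 2 (0.112). The stress response list stayed called without each library, at a camera adjusted p of at most 0.0302. With length and GC content removed together, oxidative phosphorylation kept its call in the ratio. Of the 21 other lists, WNT and Hippo-YAP had 3 members lower and mural markers 1 higher and 1 lower, adjusted over the list alone, and the rest 0 by edgeR, with 0 to 6 at an unadjusted p under 0.05 and 0 by DESeq2. Camera adjusted p-values of the 21 other lists ran from 0.0946 for collagen folding to 0.994 for mural markers. Median, mean and test differed in sign in the ratio for the integrin, WNT and Hippo-YAP, ribosomal protein, translation factor, p53, secretory, interferon, leukocyte and mural lists, and for 0 of the 5 called lists.

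Polysomal RNA differed from total RNA far more than knockdown cells differed from scramble cells. How the polysomes were isolated was not given in the sources used here. A difference in preparation between the fractions therefore cannot be told apart from a difference in ribosome loading. In scramble cells, short mRNAs stood higher and long mRNAs lower in polysomal than in total RNA. NOX4, an oxidase that TGF-beta induces, stood at 1.05 ± 0.166 CPM in total and 41.1 ± 0.450 CPM in polysomal RNA (SD, n = 2), and ID1, a target of BMP and TGF-beta receptors, at 4.80 ± 0.405 and 103.3 ± 10.7 CPM. Among the poorest in polysomes were HSPG2, the basement membrane proteoglycan perlecan (164.8 ± 18.3 CPM in total and 2.62 ± 3.04 CPM in polysomal RNA), and DCHS1, a giant cadherin (116.3 ± 7.32 and 1.61 ± 1.02 CPM). edgeR called 10293 genes, 4827 higher and 5466 lower in polysomal RNA, and DESeq2 10197. The split rests on the scaling, and with DESeq2 size factors in place of TMM it was 4652 higher and 5647 lower. Without scramble total replicate 1 the edgeR count was 7804, the lowest of such fits.

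The largest log2 fold changes among named genes in scramble cells were 5.91 for CLIC3, a chloride channel protein, 5.28 for NOX4, 5.07 for FOXS1, 4.80 for ESM1, 4.43 for ID1, 4.23 for KRT81 and 4.15 for APOC1. On the lower side stood DCHS1 at −6.15, MYO18A at −6.10, HSPG2 at −5.94, AHNAK2 at −5.75, NES at −5.68, GIGYF1 at −5.49, KMT2D at −5.30 and BCL9L at −5.25. In knockdown cells edgeR called 10230 genes, 4690 higher and 5540 lower, and DESeq2 10120. FOXS1 (5.12), NOX4 (5.10), CLIC3 (5.03), ESM1 (4.79), RPS29 (3.94), ID1 (3.89) and NPW (3.86) led there, and KIF13B (−7.15), MAP1A (−6.45), HSPG2 (−6.36), DCHS1 (−6.22), SOGA1 (−6.21), HELZ2 (−5.99) and MYO18A (−5.83) stood lowest with PPL. KIF13B, a kinesin, was at −12.1 without knockdown polysome replicate 2, since hardly any count was left, and PPL had 19.6 ± 4.01 CPM in total RNA against 2 and 0 counts in polysomes. Whether these differences themselves differed between knockdown and scramble cells is what the ratio tested.

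**Figure D3:**
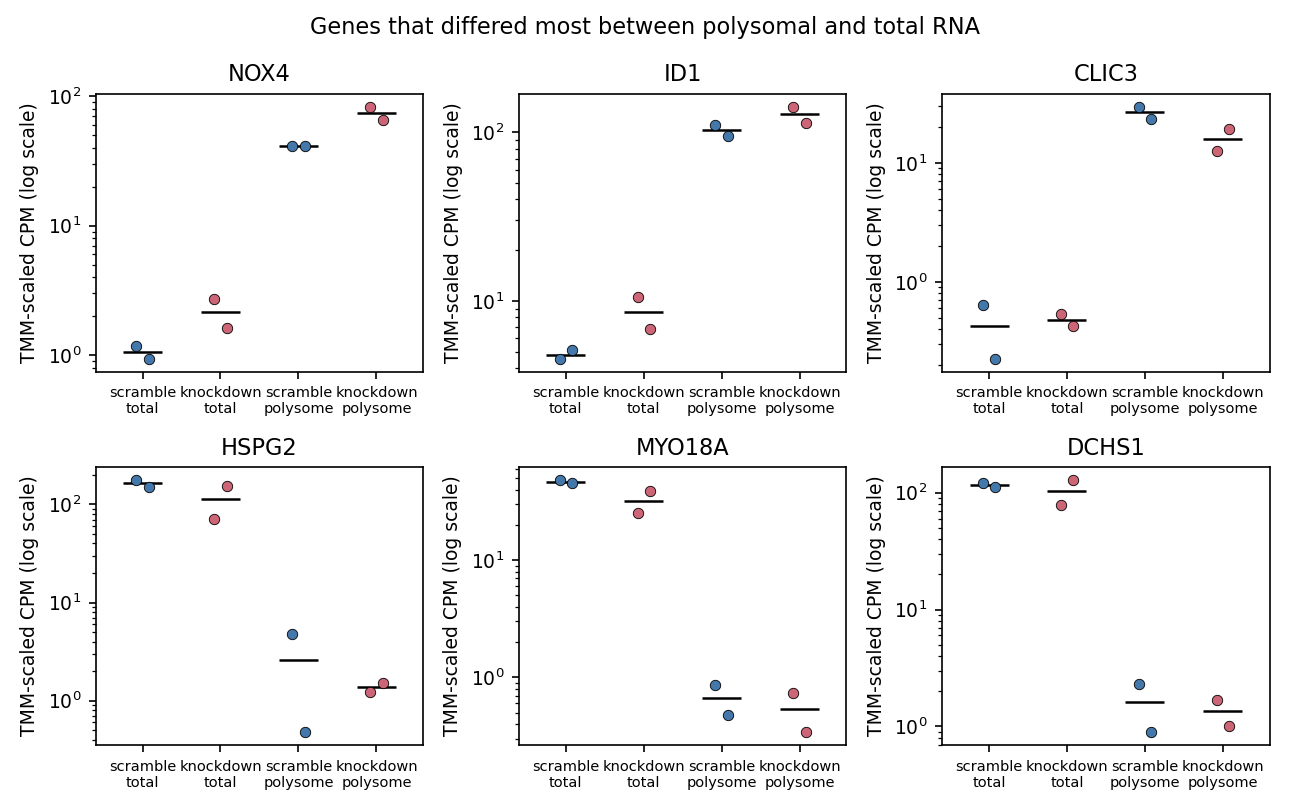
Level in TMM-scaled CPM (log axis) of 6 genes in each library of the 4 groups, with points for libraries and a line for the mean of 2. NOX4, ID1 and CLIC3 lie higher and HSPG2, MYO18A and DCHS1 lower in polysome than in total libraries for both hairpins, as with NOX4 at 1.05 against 41.1 CPM in scramble cells.

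Ribosomal protein mRNAs were higher in polysomal RNA for 75 of 76 members in scramble cells (median log2 fold change 2.89, camera adjusted p = 2.9e-38) and for 75 in knockdown cells (2.82, adjusted p = 8.26e-40), with RPS15A at 3.79 in scramble cells. With an estimated correlation camera gave an adjusted p = 0.546 in both kinds of cell for this list, and likewise for the oxidative phosphorylation, matrix and stress response lists that follow. Oxidative phosphorylation mRNAs were higher for 65 of 70 in both (medians 2.45 and 2.15, camera adjusted p = 8.11e-26 and 2.15e-22), with ATP5PF at 2.83. Matrix mRNAs were lower for 32 and higher for 10 of 45 in scramble cells (median −1.85, camera adjusted p = 5.66e-05) and lower for 31 and higher for 10 in knockdown cells (median −2.22, adjusted p = 1.13e-06). COL18A1 and COL12A1, long collagen mRNAs, stood at −3.51 and −3.84 in scramble cells, and the short microfibril gene MFAP2 at 2.51. Stress response mRNAs were higher for 23 and lower for 6 of 38 in scramble cells (median 1.16, camera adjusted p = 0.00042) and higher for 21 and lower for 8 in knockdown cells (median 0.96, adjusted p = 0.00905), with CHAC1 at 3.54 in scramble cells.

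Secretory pathway mRNAs (medians 0.48 in scramble and 0.61 in knockdown cells, camera adjusted p = 0.00261 and 0.00121), translation factors (0.61 and 0.57, camera adjusted p = 0.00897 and 0.00559), mitochondrially encoded mRNAs (2.23 and 2.60, camera adjusted p = 0.0139 and 0.000722) and p53 targets (0.53 and 0.79, camera adjusted p = 0.0403 in both) were higher in polysomal RNA (adjusted p = 0.546 to 0.620 with an estimated correlation). Growth factor receptors and their kinases were lower (medians −0.95 and −0.80, camera adjusted p = 0.00222 and 0.00559). With an estimated correlation, 0 of these 9 lists passed camera in either kind of cell (adjusted p = 0.546 to 0.620), whereas fry called them all except the mitochondrial list in scramble cells (fry adjusted p = 0.0634). In scramble cells, adjusted over the list alone, edgeR called 75 ribosomal protein, 66 oxidative phosphorylation and 11 mitochondrial members higher and 0 lower, with 0 at an unadjusted p under 0.05 on the lower side and 0, 1 and 0 lower by DESeq2. It called 10 matrix, 24 stress response, 27 secretory, 29 translation factor, 11 p53 and 7 receptor members higher, and 32, 6, 11, 12, 5 and 33 lower. In knockdown cells, adjusted over the list alone, edgeR called 75 ribosomal protein, 65 oxidative phosphorylation, 11 mitochondrial, 10 matrix, 21 stress response, 28 secretory, 30 translation factor, 12 p53 and 5 receptor members higher. The lower calls there were 0, 1, 0, 31, 8, 12, 12, 5 and 29 in the same order, and the 0 counts had 0 members at an unadjusted p under 0.05 on the lower side and 0 by DESeq2. The TGF-beta signalling list, which holds NOX4, was not called (medians −0.49 and −0.62, camera adjusted p = 0.825 and 0.650), with 12 members higher and 20 lower in scramble and 11 higher and 22 lower in knockdown cells, adjusted over the list alone. All 17 uncalled lists had camera adjusted p-values from 0.103 to 0.958 in scramble and from 0.0797 to 0.973 in knockdown cells. Median, mean and test differed in sign for the collagen folding, cytokine and cardiomyocyte lists in scramble cells and the cytokine and epithelial lists in knockdown cells.

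Transcript length ran through all of these comparisons. Across 8956 protein-coding genes, which are not independent replicates, Spearman's correlation of transcript length with the polysomal to total log2 fold change was −0.711 in scramble and −0.675 in knockdown cells. With the knockdown fold change it was −0.507 in total RNA, −0.108 in polysomal RNA and 0.228 in the ratio. The correlations with GC content were 0.413, −0.0544 and −0.335 in the same order. Median transcript length per count was 2705 nt in knockdown total replicate 1 but 2986 nt in replicate 2, within the scramble total range (2982 to 3033 nt). The trends in total RNA and the ratio may thus rest on replicate 1, and the correlation was not taken for each library. Genes in the shortest length class, 344 to 1275 nt, had a median knockdown log2 fold change of 0.22 in total RNA, and those in the longest, 7106 to 34526 nt, −0.17. In polysomal RNA the same classes had medians of 0.01 and −0.13. The ribosomal protein and oxidative phosphorylation lists hold short mRNAs, and many matrix genes, as well as FLNA and FLNC, have long ones.

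**Figure D4:**
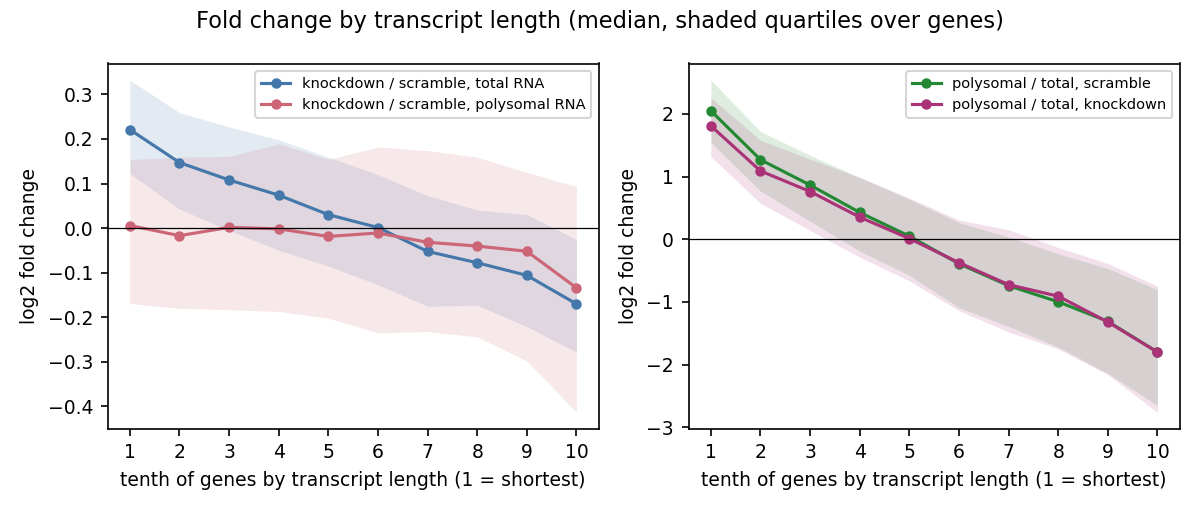
Median log2 fold change of genes (lines) with the quartiles over genes (shading) in 10 classes of transcript length, for knockdown over scramble in total and polysomal RNA (left) and polysomal over total RNA in scramble and knockdown cells (right). The total RNA line falls from 0.22 to −0.17 with length, and polysomal over total RNA falls from 2.05 to −1.80 in scramble cells. The total RNA line takes both knockdown total libraries together, and its fall may rest on replicate 1, which had the shortest transcripts.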

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

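The ratio tests of the gene lists were set beforehand, whereas the tests of transcript length, of a single polysome library and of a displaced knockdown total library were chosen only after the result was seen, and the rule of the single-library test was rewritten after its first outcome.

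By camera's test of the ratio, 5 gene lists differed between knockdown and scramble libraries in polysomal RNA beyond their difference in total RNA. These were extracellular matrix structure (camera adjusted p = 0.0127), the contractile apparatus (adjusted p = 0.0027), and the stress response, oxidative phosphorylation and mitochondrially encoded mRNAs (adjusted p = 0.00143 each). None of these 5 held with an estimated correlation (lowest adjusted p = 0.551), and fry called 0. Against the scramble polysome mean, the mitochondrial median was −0.75 and 0.75 in scramble polysome replicates 1 and 2. The medians of 0.405 and 0.728 in knockdown polysome replicates 1 and 2 lay inside that range. The list turned downward without scramble polysome replicate 1, so a single scramble library stays open as its cause.

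Matrix and contractile mRNAs were lower in knockdown polysomes, with a median log2 fold change of −0.307 over the 83 members of both lists. With the trend on transcript length removed the median was −0.251, and both lists still passed camera at the preset correlation (adjusted p = 0.0158 and 0.00422). With an estimated correlation neither passed camera before correction (adjusted p = 0.874 and 0.689), and the corrected lists were not tested in that way. The fitted length trend thus took up only part of the shift, but these calls cannot decide whether length is the whole cause. With length and GC content removed together the median over both lists was −0.202. The matrix list, whose median went from −0.416 to −0.249, then no longer passed camera at the preset correlation (adjusted p = 0.056), while the contractile list did (adjusted p = 0.0175). The 4 pairings of a knockdown with a scramble polysome library had medians from −0.446 to −0.113, all below 0, but without knockdown polysome replicate 1, which stood apart in the principal components, neither list was called, and without scramble polysome replicate 1 the matrix list was not (adjusted p = 0.564), so a single library stays open as a cause. A lower polysome association of these mRNAs after loss of EIF4G2 may be the reason, as a hypothesis that 2 libraries per group leave undecided.

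In total RNA, ribosomal protein and oxidative phosphorylation mRNAs were higher in knockdown cells, and interferon and stress response genes moved as well. The first pair rested on 1 library, since the median of knockdown total replicate 2 was −0.0931 of that of replicate 1 for ribosomal proteins and −0.149 for oxidative phosphorylation. This indicates that a displacement of knockdown total replicate 1, which also had the shortest transcripts, could account for them and for part of the fall of oxidative phosphorylation in the ratio. For the interferon list the share was 1.04 and for the stress list 0.593, so a displacement of that library is argued against as their cause. With the length trend removed both the interferon response and the integrated stress and unfolded protein response still passed camera at the preset correlation (adjusted p = 6.31e-10 and 1.56e-07). With an estimated correlation neither passed camera before correction (adjusted p = 0.464 for both), and the corrected lists were not tested in that way. These calls therefore cannot decide whether length is the whole cause, and an effect of the knockdown stays open.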

How the results depend on the processing

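The corrections for transcript length and GC content, the exclusion of mitochondrially encoded genes and the list tests without each library were chosen only after the result was seen; the other alternatives were set beforehand.

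Counts of called genes depended on the tool and the filter. In total RNA, where edgeR called 0, there were 38 genes with no filter on low counts (30065 genes tested), 26 by DESeq2, 10 with the 4 libraries of the comparison alone, 5 with the length trend removed and 3 with length and GC removed. In polysomal RNA, where edgeR called 2, there were 502 with no filter, 228 by DESeq2, 0 by glmTreat against 1.5-fold (which tests a larger change by construction) and 8 with length and GC removed. In the ratio, where edgeR called 0, there were 64 with no filter and 4 by DESeq2. Without each library in turn, the counts ran from 0 to 183 in polysomal RNA (highest without knockdown polysome replicate 2) and from 0 to 2 in the ratio, and stayed at 0 in total RNA. Such fits assume that the lone library of a group varies like the others. The cause was not tested.

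EIF4G2 kept its direction under all alternatives. In total RNA it passed the threshold with no filter (−1.366, adjusted p = 3.84e-10), by DESeq2 (−1.36, adjusted p = 4.05e-10), with 4 libraries (−1.359, edgeR adjusted p = 0.0349) and with length removed (−1.307, edgeR adjusted p = 0.0446). In polysomal RNA glmTreat did not call it (−1.599, adjusted p = 0.155), and without each library it ran from −1.906 to −1.423. STC1 in polysomal RNA lost its call under 7 alternatives. RPS21 in total RNA ran from −0.01521 without knockdown total replicate 1, where its sign turned, to 0.8097 without replicate 2.

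No list was called in total, polysomal RNA or the ratio with an estimated correlation (0, 0 and 0 by camera) or by fry (0, 0 and 0). Without each library camera called 4 to 7 lists in polysomal RNA and 3 to 6 in the ratio, against 7 and 5 with all. Directions turned for 5 list calls without 1 library, with camera adjusted p-values over the 8 fits from 1.69e-22 to 0.173 for ribosomal proteins in total RNA, 5.79e-16 to 0.277 for oxidative phosphorylation in total RNA, 2.08e-31 to 0.307 for mitochondrial mRNAs in polysomal RNA, 2.41e-11 to 0.83 for oxidative phosphorylation in the ratio and 3.82e-33 to 0.711 for mitochondrial mRNAs in the ratio. The cause was not tested beyond the displaced library weighed above. Of the other checks of list calls, 189 kept and 72 lost the call.

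With the replicate number as a replicate block, edgeR called 0 genes in total RNA, 3 in polysomal RNA and 0 in the ratio, and with a block by culture 0 in the ratio on 2 residual degrees of freedom. Deviations of libraries with the same number correlated from −0.279 to 0.166 over 9261 genes, so the numbers were not taken to pair the samples. With mitochondrially encoded genes left out the counts were 0, 2 and 0. The fraction counts stayed within 1.5 times under the alternatives run for them, which did not include the length and GC corrections or the fit of 4 libraries alone. Depth limits PPL and EME2, with 0 to 2 counts in the knockdown polysome libraries, to an interval and a bound.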

Other observations

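The tests of TGF-beta induced and repressed genes, and the sterol checks with an estimated correlation, in polysomal RNA and after the length and GC correction, were chosen only after the result was seen, while the tests of upstream AUGs and of sterol and hypoxia lists were set before their results were seen.

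Genes of sterol synthesis and uptake stood lower in knockdown total RNA. The list was prompted by HMGCS1, INSIG1 and SCD among the DESeq2 calls and leaves these out. Of its 23 members, 20 lay below 0, with a median log2 fold change of −0.239, below all 10000 random lists matched on expression (middle 95% from −0.0259 to 0.182). The median ran from −0.315 to −0.154 over the 4 pairings of knockdown and scramble total libraries, was −0.298 after removal of length and GC trends and was −0.328 in polysomal RNA. Camera gave a p of 7.19e-07, or 0.0409 with an estimated correlation, both unadjusted. This is consistent with lower sterol synthesis gene expression after EIF4G2 knockdown, as a hypothesis found and tested on the same libraries.

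A hypoxia list was prompted by VEGFA, ANGPTL4, SLC16A3 and STC1 and leaves these out. Its 21 members had a median of 0.124 in total RNA, at percentile 84.2 of matched random lists (middle 95% from −0.0672 to 0.181), so a joint rise of hypoxia genes was not borne out. A further hypothesis was that mRNAs with an AUG upstream of their coding sequence lose polysome association without EIF4G2. With length, GC content and expression in the model, the upstream AUG term ran from 0.0438 to 0.0951 over the 4 pairings of polysome libraries (8536 genes, 4383 with an upstream AUG), opposite in sign to that hypothesis, and genes are not independent replicates. These terms were fitted to polysomal levels, which also carry any change in total RNA. Fitted to the ratio, which was not part of the rule set beforehand, the term was 0.0527 ± 0.00701 (SE over genes).

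Genes known to be induced by TGF-beta stood higher in polysomal than in total libraries. Their median was 1.87 on the log2 scale over 28 genes, as the mean of scramble and knockdown cells. The list was assembled after at least 11 of its members, NOX4 and ID1 among them, were seen. The TGF-beta signalling list set beforehand had medians of −0.49 and −0.62 and was not called. After removal of the length trend the median of the induced genes was 1.58, which the choice of members after seeing them could have raised. For the 17 genes left without 11 of the members seen first, it was 1.17, at percentile 99.5 of 10000 matched random lists (middle 95% from −0.183 to 0.959). That reading was relied on only after its value was seen. The 17 were not all unseen either. COL1A1, COL4A1, COL5A1 and FN1 among them had been called in this comparison within the matrix list. CNN1 and TPM1 had been called within the contractile list, and SKIL and CCN2 within the TGF-beta signalling list. Before the length correction, CNN1, TPM1, CCN2 and SKIL stood higher in polysomal RNA, and FN1 and the collagens lower. The 17 genes are therefore no independent check, and whether length is the whole cause stays open. A stronger TGF-beta response in the cells of the polysome libraries could also give the higher level of the induced genes. The 8 repressed genes, with a median of −0.724 at percentile 8.95 (middle 95% from −1.18 to 1.04), were too few to decide. These tests were first run on genes above a minimum level, which was dropped because fewer than 80% of the repressed genes passed it. Higher ribosome loading of the induced mRNAs stays open as a biological explanation, but cannot be told apart from a difference in preparation between the fractions.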
